A study of Mus musculus with 3 samples.

How the data were processed

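Single-cell RNA was measured in 3 libraries of sorted mouse myeloid cells, control blood, control tumor and Treg-depleted tumor, 1 library per group. Per the submitters' processing notes, the data were processed with Cell Ranger 1.2 against mm10. The matrices deposited by the authors hold whole-number UMI counts, unit count, for 27998 genes and all 737280 barcodes of the kit, so cells were called anew. Gene identifiers were matched to GENCODE M21 (GRCm38), which held 27722 of the 27998, and where a symbol named several identifiers the one with the most UMIs was used for lists and named genes (27933 symbols, 65 duplicates). Genes with near-identical copies, such as members of the H2-Q and Ifit families, share sequence, and their counts depend on how reads were assigned upstream. The labels give no animal numbers, pooling or batches.

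A barcode was kept with a UMI total of at least 10% of the 99th percentile of the 3000 largest totals of its library (1010, 3490.3 and 1565 UMIs for control blood, control tumor and Treg-depleted tumor), at least 400 genes and at most 10% mitochondrial UMIs. Of 5578, 3842 and 3935 barcodes above the UMI threshold, 5539, 3827 and 3907 passed. Doublets were scored by the share of simulated doublets among nearest neighbours, and 245, 117 and 122 cells were removed, an expected rate of 0.8% per 1000 cells. Cells kept held 79.4%, 82.9% and 76.2% of the 22944387, 42493416 and 23291061 UMIs of the libraries, with medians of 1418.5, 2076.5 and 1455 genes and 2.37%, 2.10% and 2.68% mitochondrial UMIs. Medians of 3500.5, 7239.5 and 4112 UMIs per cell leave a gene at a few CPM uncounted in most single cells, so levels were taken over classes. In tests on these data, 211, 148 and 151 planted doublets were removed at 63%, 37.8% and 41.7%, with 2.1%, 1.7% and 1.6% of other cells.

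The 3 libraries were clustered together without batch correction: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden resolution 1 with seed 1. Each cluster was named separately in each library with at least 15 of its cells, from 18 fixed marker lists (185 of 189 genes found), with at least 3 markers at 20 CPM or more. A name outside the monocyte-to-macrophage lineage also needed 2 of its markers among the 10 leading genes. Genes of at least 50 CPM were ranked for this by CPM over the mean CPM of the library's other clusters, with 5 added to each. Parts whose leading genes pointed to another class, or whose name differed from most of their cluster, were left unnamed. The monocyte and macrophage lists counted as 1 class for this. Parts with under 15 cells were unnamed too, and in the control tumor only such parts were. Unnamed cells numbered 174 in blood, 16 in the control tumor and 66 in the Treg-depleted tumor (3.29%, 0.43% and 1.74%). In libraries where a cluster fitted macrophages best, lineage clusters were split by the difference between the macrophage and the classical monocyte score, each a mean z score over the clusters of the same library. Differences above 0.5 gave macrophage-like, below −0.5 monocyte-like and between them intermediate cells. This margin was set after the data had been seen, and the intermediate class held 43.8% of control and 70.3% of Treg-depleted tumor cells. Small classes were basophil-like (0.64%) and plasmacytoid DC-like cells (0.38%) in blood, and CCR7 DC-like cells in the tumors (0.73% and 0.42%).

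Counts were summed over a class per library and divided by the class total. Log2 ratios of these CPM values carry exact Poisson intervals, shares Clopper-Pearson intervals, both at 95%. A gene with 0 counts was set to a floor of 3 counts over the class, and the fold of a named gene is then a lower bound. For scarce list members this need not hold. In macrophage-like cells of the Treg-depleted tumor the floor was 1.95 CPM. A list member needed only 20 UMIs among the 14534049 of the control class, so it could be scored as higher with 0 Treg-depleted counts. How many members this touched was not counted. Classes with at least 50 cells in both libraries were compared. With 1 library per group no test between groups was made. Each of 18 gene lists (417 of 419 genes found) is given by the median log2 ratio of its members with at least 20 UMIs in either library, where at least 5 had that many, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists drawn from 25 expression bins. The percentile describes these libraries only. Shares of cells with a UMI were taken after thinning each cell to 1500 UMIs, which left out 490 blood cells and no tumor cell.

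Before the data were examined, the groups, comparisons, filters, lists, markers, named-gene rule and most alternatives were fixed. Per comparison, genes were ranked by CPM ratio among those with at least 50 CPM and 100 UMIs in the higher library. The text names some of the 12 with the largest and the 12 with the smallest ratio, not all of them. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and predicted genes, and markers of other cell types, were left out of that ranking. Up to 4 members per list were added, and Arg1, Ly6c2, Ccr2, C1qa, Apoe, Cxcl9, Mrc1, Foxp3 and Xist were always eligible. The haemoglobin gene Hbb-bs was chosen after its values had been seen, as were the genes named as leading a cluster.

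On simulated counts with known ratios, 95.7% of 8105 and 95.3% of 8855 intervals held the true value, a planted list reached percentile 100.0, and 8 and 6 of 100 null lists fell outside the central 95%. These counts were Poisson draws, which the intervals assume, so the run checks the calculation only. Variation between cells and list members that move together were not simulated.

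The alternatives changed 1 choice at a time, with 1 exception: a fixed minimum of 1000 UMIs and 200 genes, no doublet removal, at most 5% mitochondrial UMIs, Leiden resolution 0.5, clustering without the response lists, scaling by the median of gene ratios, the mean over cells of CPM, every detected list member, and subtraction of the profile of barcodes with 10 or fewer UMIs. The exception is the first, which changed the UMI and the gene minimum together and is called the fixed minimum of 1000 UMIs. After the data had been seen, 5 more were added: intermediate cells counted as macrophage-like, a split at a z difference of 1, the control tumor cells of cluster 9 counted as monocyte-like, blood cluster 5 left out, and ambient subtraction at the share seen in cells outside the lineage. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.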

Results

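Myeloid cells sorted from mice bearing subcutaneous B16-F10 melanoma were compared as 3 single-cell libraries: blood and tumor of control mice, and tumor of mice depleted of regulatory T (Treg) cells. Each group had 1 library, so no p-value, standard error or count of changed genes is given. Brackets hold 95% counting intervals, which cover the sampling of molecules or cells and not the difference between animals. Gene levels are counts scaled to the total of the class (CPM), and where none is given the counting interval of the ratio excluded 1 unless stated. The Treg-depleted mice also carried the FoxP3 DTR allele, so depletion and genotype cannot be separated. After filtering, 5294 blood, 3710 control tumor and 3785 Treg-depleted tumor cells remained, with medians of 3500.5, 7239.5 and 4112 unique molecules (UMIs). The sort removed CD90-positive cells, and Foxp3, the gene of the depleted cells, had 0 UMIs in every class compared (upper limits 0.119 CPM in the control and 0.241 CPM in the Treg-depleted tumor over all monocyte-to-macrophage cells), so it says nothing on the depletion itself. Xist, the transcript of the inactive X chromosome, also had 0 UMIs in those cells.

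Blood myeloid cells were mostly monocytes, and tumor myeloid cells were mostly named monocyte-like, intermediate or macrophage-like, beside dendritic cells. Intermediate means only that the macrophage and monocyte scores of a cluster lay close together, and no ordering of cells was computed. Classes were named from marker genes, and the monocyte-to-macrophage clusters of each tumor were placed relative to the other clusters of the same library. Shares are therefore given per library with no direction between libraries, and the sort, the UMI threshold of each library (1010, 3490.3 and 1565 UMIs) and the gap in depth all bear on them. In blood, 46.0% of cells (44.6 to 47.3; clusters 2, 5 and 14) were monocyte-like, 33.2% (31.9 to 34.5) nonclassical monocyte-like and 9.39% (8.62 to 10.2) resembled type 2 conventional dendritic cells (cDC2-like). Cluster 5, with 799 cells, matched the classical monocyte list best but scored higher on macrophage (1.39) than on classical monocyte markers (0.30) relative to the other blood clusters, and its leading genes included the macrophage markers C1qb and Ms4a7. NK cell-like, neutrophil-like and B cell-like cells made up 3.12%, 2.25% and 1.76% of the blood library. In the control tumor, 17.0% (15.8 to 18.3; cluster 8) were monocyte-like, 43.8% (42.2 to 45.4; mainly cluster 1) intermediate and 26.1% (24.7 to 27.5; clusters 7 and 12) macrophage-like. Dendritic cells of that tumor were cDC2-like (7.14%, 6.34 to 8.02), cDC1-like (3.05%) and plasmacytoid DC-like (1.75%). The Treg-depleted tumor held 11.7% monocyte-like (10.7 to 12.8; cluster 9), 70.3% intermediate (68.8 to 71.8; clusters 0 and 3) and 8.19% macrophage-like cells (7.34 to 9.11; mainly cluster 13). It also held 3.51% cDC2-like (2.95 to 4.15), 1.03% cDC1-like and 3.06% neutrophil-like cells. Its macrophage-like cluster 13 scored 0.68 on macrophage markers, little above the intermediate cluster 3 (0.59), but 0.11 against 0.86 on classical monocyte markers. Against cluster 3 its name thus rested mainly on lower monocyte markers. C1qa (387 against 430 CPM), C1qb (299 against 677) and Apoe (68.4 against 141) were lower in cluster 13. Mrc1 (671 against 630) and Ms4a7 (77.7 against 28.3) were higher in it. Clusters with under 15 cells in a library were not named there, so a class missing from a library is not shown to be absent.

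The macrophage-like share within the lineage was 30.0% (28.4 to 31.6) of 3224 control tumor cells and 9.08% (8.14 to 10.1) of 3415 Treg-depleted tumor cells. Most other lineage cells were intermediate, 50.4% (48.7 to 52.2) and 77.9% (76.5 to 79.3). The line between the classes set these shares: over the alternatives tried they ran from 18.3% to 80.4% in the control tumor and from 0% to 87.0% in the Treg-depleted tumor. The lineage clusters of the tumors each came mostly from 1 library, so a cluster may stand for its library.

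Monocyte-like cells of the control tumor carried an inflammatory programme that those of control blood nearly lacked. Chemokine genes, inflammatory cytokines and their NF-kB-driven partners, interferon gamma response genes and genes of matrix remodelling were all higher in the tumor. The chemokine receptor genes Ccr2 and Cx3cr1 and the trafficking regulator gene Klf2 were lower there, while the trafficking list as a whole lay inside the range of random lists. The comparison used 631 tumor and 2435 blood cells. Over the 9481 genes measured the median log2 ratio of tumor over blood was −0.50, and each list was read against 10000 random lists matched on expression.

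Chemokines had a median log2 ratio of 6.06 (5.45 to 6.23), with 16 of 18 members at least 2-fold higher, and over the alternatives it ran from 5.35 to 7.48. Inflammatory cytokines and NF-kB targets had 5.74 (5.59 to 5.89; 5.05 to 6.88 over the alternatives), with 24 of 24 members at least 2-fold higher. Medians were 2.82 (2.67 to 2.96) for interferon gamma response genes, 2.88 (2.79 to 2.98) for matrix remodelling, 2.41 (2.20 to 2.60) for T cell co-signalling ligands and 1.55 (1.42 to 1.64) for the oxidative stress response. Heat shock and immediate early genes had 1.14 (0.94 to 1.25) and lysosome and lipid handling genes 1.09 (1.03 to 1.14). All 8 of these lists lay above every random list, and the unfolded protein response (0.94, 0.84 to 1.03) lay at percentile 99.96. Lists nearer the random range were MHC class I (0.46, percentile 98.6), hypoxia and glycolysis (0.33, 99.7), MHC class II (−0.02, 91.3), leukocyte trafficking (−0.22, 52.2), oxidative phosphorylation (−0.26, 17.0) and the type I interferon response (−0.30, 25.03). Ribosomal protein genes had −0.43 (percentile 0.46), and 0.07 when scaled by the median of gene ratios. Alternative activation genes had 0.46 (percentile 99.9), between 0.05 and 1.26 over the alternatives. Without blood cluster 5 the medians were 5.88 for chemokines and 5.97 for inflammatory cytokines, but 2.12 for MHC class II, 1.22 for alternative activation and −0.53 for trafficking, so the last 3 depended on the make-up of the blood class.

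The neutrophil-attracting chemokine gene Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) stood at 3267 CPM (3205 to 3331) in tumor and 3.30 CPM (2.24 to 4.68) in blood monocyte-like cells. With cells thinned to 1500 UMIs, 57.1% (53.1 to 61.0; 77.3% unthinned, median 4677 UMIs) of tumor and 0.33% (0.14 to 0.65; 0.57% unthinned, median 3815 UMIs, 10 cells left out) of blood monocyte-like cells had a Cxcl2 UMI. The background share in plasmacytoid DC-like cells of the tumor was 15.4% (32.3% unthinned, median 4936 UMIs). Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), which encodes the prostaglandin synthase COX-2, had 538 UMIs in tumor and 1 in blood, a log2 ratio of 10.64 (8.15 to 15.94). Inhba, encoding the activin A subunit, had 679 UMIs (214 CPM, 198 to 231) against 0, at least 670.0-fold higher with 3 UMIs as the floor. Higher in tumor as well were the itaconate synthase gene Irg1 (543 against 0.426 CPM), the thrombospondin gene Thbs1 (2108 against 3.30), the maturation marker Cd83 (838 against 1.49), the cystine transporter gene Slc7a11 (731 against 2.77) and Cd274, which encodes the inhibitory ligand PD-L1 (282, 264 to 301, against 2.34, 1.47 to 3.54). Among interferon-inducible chemokines, Cxcl9 stood at 406 against 4.79 CPM and Cxcl10 at 2436 against 60.8 CPM. The type I interferon list split, with the ubiquitin-like modifier gene Isg15 higher in tumor (1035 against 390.0 CPM) and the antiviral gene Ifit3 lower (32.1 against 177 CPM).

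Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), the receptor for the monocyte chemoattractant CCL2, stood at 322 CPM (303 to 343) in tumor and 1742 CPM (1716 to 1769) in blood. Cx3cr1, the fractalkine receptor gene, stood at 22.99 against 266 CPM and Klf2, which encodes a transcription factor of quiescent circulating leukocytes, at 48.8 against 835 CPM. The monocyte surface marker gene Ly6c2 was lower in tumor (842 against 1493 CPM), as was the lipid carrier gene Apoe (2334 against 3852 CPM), whose log2 ratio was −0.18 without blood cluster 5. The complement gene C1qa (63.0 against 14.8 CPM) was read as background, since cDC1-like cells of the tumor held 89.1 CPM. The mannose receptor gene Mrc1 (11.7 against 11.8 CPM) and the arginase gene Arg1 (20 against 1 UMIs) were both scarce, and the interval of the Mrc1 ratio held 1.

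**Figure D1:**
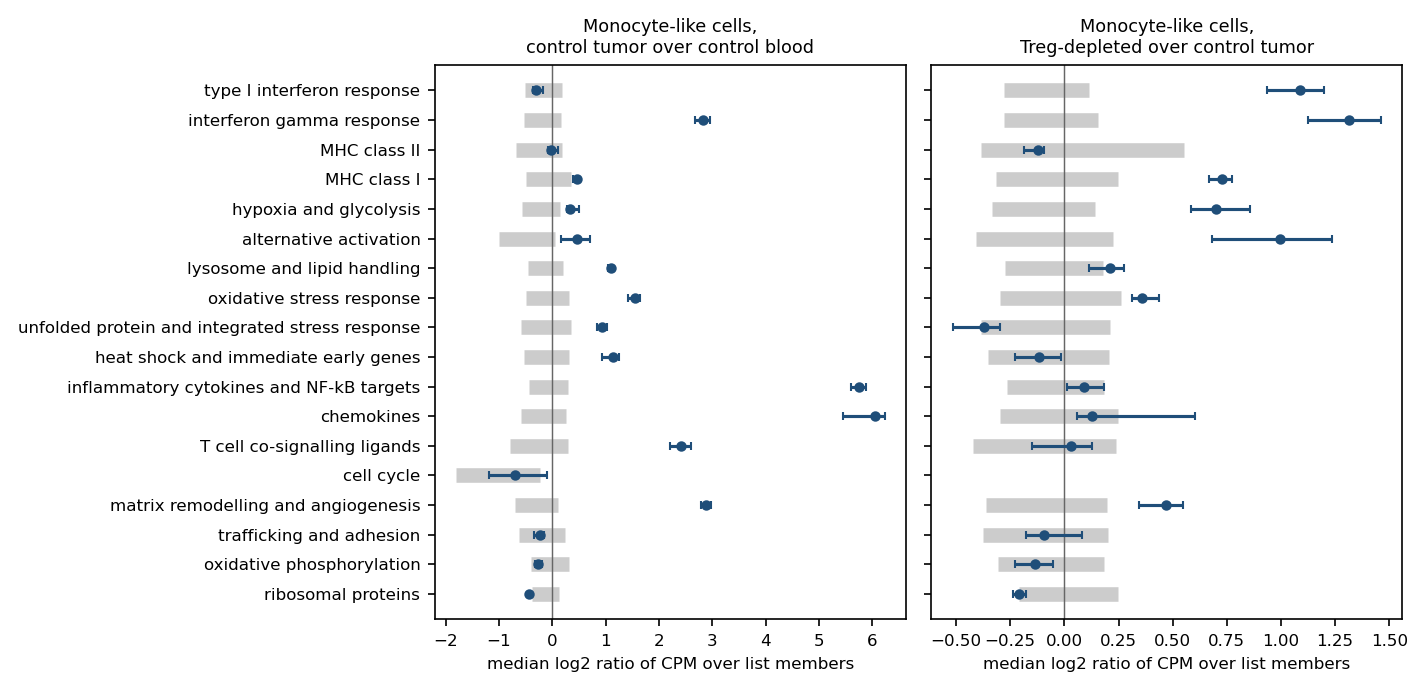
Median log2 ratio of CPM over the members of each gene list in monocyte-like cells, control tumor over control blood (left) and Treg-depleted over control tumor (right); dots give list medians with 95% counting intervals and grey bars the central 95% of 10000 expression-matched random lists. Chemokines (6.06) and inflammatory genes (5.74) stood highest on the left, and interferon gamma (1.32) and type I interferon response genes (1.09) on the right, where the cell cycle list had too few members to place.

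Monocyte-like cells of the Treg-depleted tumor had higher interferon-inducible genes than those of the control tumor, by an amount that rested on which control tumor cells were counted as monocyte-like. The medians of the inflammatory and chemokine lists lay inside the random range, with single members far higher or lower. Alternative activation genes, led by Arg1 and the eosinophil-attracting chemokine gene Ccl24, were also higher, as were MHC class I and hypoxia genes. The lipid carrier gene Apoe was lower, and Ly6c2 was higher. Here 443 Treg-depleted and 631 control tumor cells were compared over 6851 genes, whose median log2 ratio was −0.14.

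Interferon gamma response genes had a median log2 ratio of 1.32 (1.13 to 1.46), with 18 of 33 members at least 2-fold higher and none 2-fold lower. Over the alternatives it ran from 0.86, with response genes left out of the clustering, to 1.45. Type I interferon response genes had 1.09 (0.93 to 1.2) and 18 of 34 members at least 2-fold higher, with 0.71 when response genes were left out. The class was cluster 9 in the Treg-depleted and cluster 8 in the control tumor, and interferon-inducible genes were among the leading genes of cluster 9. The 96 control tumor cells of cluster 9 were named intermediate and so were not in the comparison. With them counted as monocyte-like the medians were 0.96 for interferon gamma and 0.39 for type I response genes, and among intermediate cells the type I median was −0.30. The size of the type I difference thus rested on the line between the classes. Alternative activation (1.00, 0.68 to 1.24; 0.60 to 1.41 over the alternatives), MHC class I (0.73, 0.67 to 0.77) and hypoxia and glycolysis (0.70, 0.59 to 0.86) also lay above every random list, and matrix remodelling (0.47) lay at percentile 99.97. Chemokines (0.13, percentile 90.5), inflammatory cytokines (0.09, 91.4), co-signalling ligands (0.03, 77.3), trafficking (−0.10, 54.2), heat shock genes (−0.12, 41.4), MHC class II (−0.12, 31.5) and oxidative phosphorylation (−0.14, 29.3) lay inside the random range. Oxidative stress genes had 0.36 (percentile 99.3), lysosome and lipid handling genes 0.21 (98.7), ribosomal protein genes −0.21 (2.61) and the unfolded protein response −0.37 (2.98).

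Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), an interferon-inducible GTPase gene of defence against intracellular parasites, stood at 711 CPM (675 to 748) in Treg-depleted and 41.3 CPM (34.5 to 49.0) in control tumor monocyte-like cells. The antiviral genes Rsad2 (725.5 against 149 CPM) and Ifit2 (136 against 15.1) and the class I gene H2-Q7 (372 against 75.6) were higher with Treg depletion. With the 96 cells counted as monocyte-like the log2 ratio was 2.91 for Iigp1 but 0.41 for Rsad2 and 0.47 for Ifit2. So were the checkpoint ligand genes Cd274 (702 against 282 CPM) and Pdcd1lg2 (95.1 against 13.5). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a T cell attractant induced by interferon gamma, did not follow its list: it stood at 443 CPM (415.5 to 473) against 406 (384 to 429), and its log2 ratio of 0.13 became −0.22 with at most 5% mitochondrial UMIs. Arg1, which consumes arginine, stood at 763 CPM (726 to 802) against 6.30 (3.85 to 9.73), and Ccl24 at 1336 (1287 to 1387) against 59.5 (51.3 to 68.7). Both exceeded the 255 and 355 CPM of the neutrophil-like cells of that tumor, though Arg1 not the 798 CPM of its 16 CCR7 DC-like cells. The thinned share of cells with a UMI was 28.2% for Arg1 and 33.6% for Ccl24. These lay within the counting intervals of the background share in the neutrophil-like cells (13 to 28.3% and 30.7 to 49.2%). Arg1 lay just under its upper limit. No share of producing cells is therefore given. The arginine transporter gene Slc7a2 (115 against 6.61 CPM), the nitric oxide synthase gene Nos2 (65.5 against 1.89) and the haem oxygenase gene Hmox1 (1538 against 492) were higher too.

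Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) stood at 270.5 CPM (249 to 294) in Treg-depleted and 2334 CPM (2281 to 2387) in control tumor monocyte-like cells. Other genes lower with Treg depletion were the ion channel genes Tmem176b (12.9 against 197.5 CPM) and Tmem176a (13.9 against 116), the neutrophil attractant gene Cxcl1 (18.6 against 143) and the cytokine gene Il1b (3156 against 7993). Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970) stood at 2817 CPM (2746 to 2890.0) against 842 (811 to 875), while Ccr2 stood at 166 against 322 CPM. C1qa (47.3 against 63.0 CPM) was at background in the control tumor, while cDC1-like and neutrophil-like cells of the Treg-depleted tumor held only 4.80 and 20.1 CPM. Its log2 ratio of −0.41 became 4.90 with ambient RNA subtracted at the share seen outside the lineage, so no direction is given. Mrc1 (23.4 against 11.7 CPM) had a log2 ratio of 1.01 that became −3.94 with ambient RNA subtracted.

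Across the whole lineage of monocyte-like, intermediate and macrophage-like cells, Treg-depleted tumor cells had higher alternative activation genes and lower MHC class II and cell cycle genes. Apoe and the complement gene C1qa were far lower in the Treg-depleted tumor, and Arg1, Ccl24 and the resistin-like gene Retnla were far higher. Genes usually grouped as markers of alternative activation and genes usually grouped as tumor macrophage markers thus lay on opposite sides of the comparison. This comparison was added after the classes were seen, because it needs no line between monocytes and macrophages. That of the intermediate class was added then as well, and does rest on that line. It held 3415 against 3224 cells and 10968 genes.

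Alternative activation had a median log2 ratio of 1.56 (1.36 to 1.62), with 13 of 20 members at least 2-fold higher and 3 at least 2-fold lower. Among those 3 was Il10, the gene of an anti-inflammatory cytokine, at 5.75 CPM (4.61 to 7.08) in the Treg-depleted and 101 CPM (97.2 to 104) in the control tumor. Matrix remodelling (0.82, 0.71 to 0.94), hypoxia and glycolysis (0.76, 0.70 to 0.78) and interferon gamma response genes (0.71, 0.65 to 0.75) were higher. With a Leiden resolution of 0.5 the interferon gamma median was 0.00, and with at most 5% mitochondrial UMIs the hypoxia median was 0.29. In these settings 1898 of 3785 and 1021 of 3471 Treg-depleted tumor cells were unnamed, against 66 here, so the lineage held far fewer cells. Cell cycle genes had −1.79 (−2.23 to −1.65), with 22 of 24 members at least 2-fold lower, and ran from −2.61 to −0.67 over the alternatives. MHC class II (−1.26, −1.28 to −1.21) and lysosome and lipid handling (−0.63, −0.65 to −0.49) were lower. The 3 lower and 4 higher lists lay beyond every random list. The type I interferon response had 0.32 (percentile 99.7) and co-signalling ligands −0.42 (1.66). Chemokines (0.22, 93.4), trafficking (0.17, 92.3), MHC class I (0.12, 83.9), inflammatory cytokines (0.09, 81.7), heat shock genes (0.08, 79.7), oxidative stress genes (−0.02, 54.0), the unfolded protein response (−0.16, 27.8), ribosomal protein genes (−0.22, 4.78) and oxidative phosphorylation (−0.22, 7.71) lay inside the random range. Among the marker lists of other cell types, melanoma markers (−1.61, percentile 0.88), CCR7 DC markers (−1.36), nonclassical monocyte markers (−1.13) and cDC1 markers (−0.79, percentile 0.16) were lower and neutrophil markers (1.07) higher. Over the alternatives melanoma markers ran from −2.99 to −1.06, CCR7 DC markers from −2.91 to −0.33 and neutrophil markers from 0.58 to 3.70. Within macrophage-like and intermediate cells, CCR7 DC markers (0.48 and −0.10) and cDC1 markers (−0.14 and −0.55) lay inside the random range. Lineage sums weight the classes by UMIs. Macrophage-like cells gave 14534049 of 31013042 UMIs in the control and 1536563 of 15314421 in the Treg-depleted tumor. The lineage medians of these DC lists can thus follow the mixture of classes.

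Apoe stood at 148 CPM (142 to 154) in the Treg-depleted and 4328 CPM (4305 to 4351) in the control tumor, 29.2-fold lower. Macrophage markers had a median log2 ratio of −2.24, with 10 of 14 at least 2-fold lower and 2, Mrc1 among them, at least 2-fold higher: C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), a subunit of complement C1q, stood at 295 CPM (287 to 304) against 2046 (2030 to 2062), the lipid receptor gene Trem2 at 67.5 against 209.5 and the tetraspan gene Ms4a7 at 52.0 against 477. The class II gene H2-Ab1 stood at 3530 CPM (3500 to 3560) against 9216 (9182 to 9249), and Stmn1, a tubulin-binding gene of dividing cells, stood at 21.8 against 118. In the other direction, Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) stood at 4901 CPM (4866 to 4936) against 277 (271 to 283), 17.7-fold higher. Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049) stood at 5469 CPM (5432 to 5506) against 49.2 (46.8 to 51.8), 111-fold higher, and Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461) at 1184 CPM (1167 to 1201) against 68.0 (65.2 to 71.0). The chitinase-like gene Chil3 (2609 against 323 CPM), Mrc1 (355 against 107), the metalloelastase gene Mmp12 (1329 against 215) and the collagenase gene Mmp13 (596 against 54.8) were higher. Nos2, a marker usually opposed to Arg1, was higher as well (177.5 against 12.03 CPM). These values pool unlike clusters of the Treg-depleted tumor, mainly 0 (1459 cells) and 3 (1203 cells). In clusters 0 and 3 Nos2 stood at 341 and 55.1 CPM and Mmp12 at 2885 and 169. Retnla stood there at 176 and 2395 and Mrc1 at 151 and 630, so a single shared state is not shown. Control tumor cells of cluster 0 (56 cells) held Mmp12 at 1900 CPM, so another mixture of clusters could reach its pooled level. Ly6c2 stood at 1228 against 515 CPM, Cxcl9 at 166 against 502 CPM, and Ccr2 at 145 against 155 CPM, where the log2 ratio of −0.10 became 0.16 with a Leiden resolution of 0.5.

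Arg1 and Apoe differed in most cells of the intermediate class. With cells thinned to 1500 UMIs, 88.5% (87.2 to 89.7; 93.5% unthinned, median 3939.5 UMIs) of Treg-depleted and 13.8% (12.2 to 15.6; 22.3% unthinned, median 6987.5 UMIs) of control tumor intermediate cells had an Arg1 UMI. The background was 19.8% (28.4% unthinned, median 2256 UMIs) in neutrophil-like cells of the Treg-depleted tumor. For Apoe the shares were 10.3% (9.16 to 11.5; 17.7% unthinned) and 67.4% (65.1 to 69.7; 90.7% unthinned), against a background of 3.45% in those neutrophil-like cells and 18.5% in plasmacytoid DC-like cells of the control tumor. Within the intermediate class (2662 against 1626 cells) alternative activation had a median log2 ratio of 1.66, MHC class II −1.37, cell cycle −0.88, the interferon gamma response 0.40 and the type I interferon response −0.30. Macrophage markers (−1.77) and nonclassical monocyte markers (−1.53) lay below every random list in that class, and neutrophil markers (2.36) above. The intermediate classes of the 2 tumors were thus not alike in their macrophage markers. Ccl24 stood there at 6384 against 71.8 CPM and Retnla at 1235 against 53.6 CPM. The control part of the class held only 74 cells with a Leiden resolution of 0.5 and 68 without the response lists, and the log2 ratio of C1qa, −2.07, became 0.22 with that resolution.

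**Figure D2:**
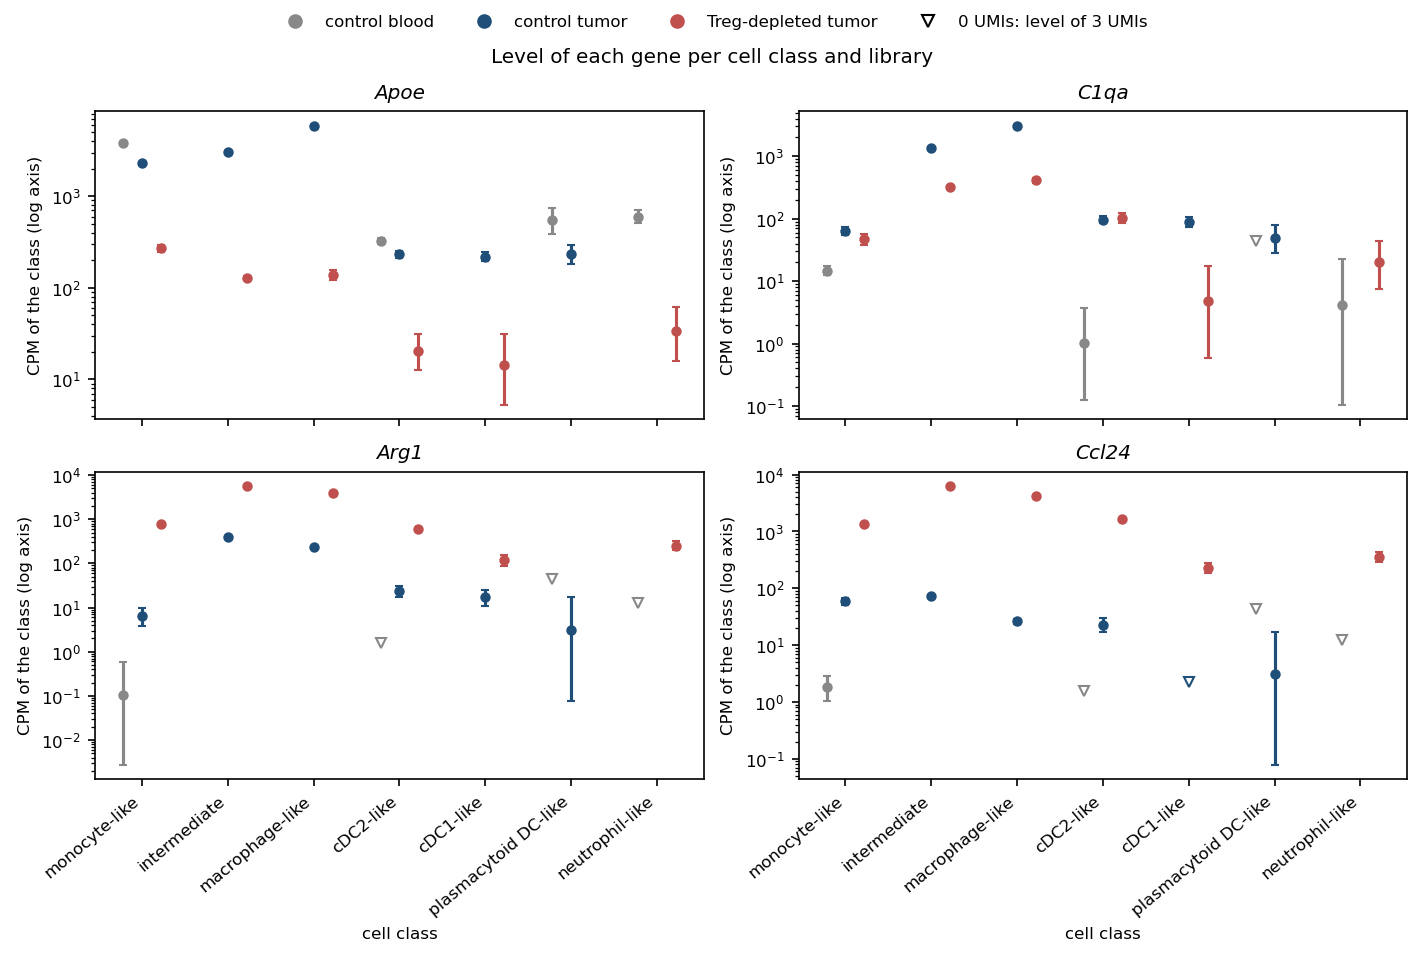
Level of Apoe, C1qa, Arg1 and Ccl24 in CPM (log axis) in each cell class (horizontal axis) of control blood (grey), control tumor (blue) and Treg-depleted tumor (red); dots carry exact 95% Poisson intervals and open triangles mark the level of 3 UMIs where none was counted. Apoe in intermediate cells stood at 3070.0 CPM in the control and 127 CPM in the Treg-depleted tumor, and Arg1 at 388 and 5775 CPM.

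Macrophage-like cells of the Treg-depleted tumor had higher alternative activation genes and lower C1qa and Apoe transcripts than those of the control tumor. They also had more of the chemokine transcripts Ccl17 and Ccl24. Ccl17 is a cDC2 marker too. The cDC2 markers had a median log2 ratio of 0.30 (percentile 78.3), with 4 of 10 at least 2-fold higher and 1 at least 2-fold lower. CCR7 DC markers had 0.48 (percentile 88.4), so both medians lay inside the random range. The macrophage markers as a list were lower and the classical monocyte markers higher, so the classes given the same name were not alike in the genes that define them. The class rested on 310 cells with a median of 4296 UMIs against 967 cells with a median of 13221 UMIs, and its make-up moved with the cell filter and the clustering. Over 10106 genes the median log2 ratio was 0.10.

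Alternative activation had a median log2 ratio of 1.78 (1.66 to 1.96), with 14 of 19 members at least 2-fold higher, between 0.46 and 2.03 over the alternatives. Matrix remodelling had 1.48 (1.22 to 1.60) but −0.11 both with a fixed minimum of 1000 UMIs and with a Leiden resolution of 0.5. Cell cycle genes had −1.33 (−1.84 to −1.10) but 2.26 with that resolution, and MHC class II −0.99 but 0.29 with that minimum. Lysosome and lipid handling genes had −0.56 (percentile 0.10), with 5 of 27 members at least 2-fold higher and 10 at least 2-fold lower. Macrophage markers, C1qa and Apoe among them, had −2.07 (−2.36 to −1.99), with 11 of 14 at least 2-fold lower, and classical monocyte markers 0.88 (0.75 to 0.995), but −0.11 with a Leiden resolution of 0.5. The medians of hypoxia (0.58, percentile 99.5), the interferon gamma response (0.57, 99.4), co-signalling ligands (−0.57, 0.32) and ribosomal proteins (−0.55, 0.59) also lay outside the random range. Inside it lay heat shock genes (0.47, 96.8), the unfolded protein response (0.39, 92.3), chemokines (0.22, 85.6), type I interferon (0.22, 68.6) and inflammatory cytokines (0.11, 65.9).

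Arg1 stood at 3889 CPM (3791 to 3988) in Treg-depleted and 235 CPM (227 to 243) in control tumor macrophage-like cells, Ccl24 at 4140.0 against 26.4 CPM, Retnla at 2360.0 against 95.9 and Chil3 at 1152 against 49.0. Apoe stood at 139 CPM (121 to 158.5) against 5915 (5876 to 5955), a log2 ratio of −5.42, C1qa at 410.0 against 3102 CPM and the prostaglandin D synthase gene Hpgds at 1 against 1132 UMIs, a log2 ratio of −6.90 (−12.21 to −4.42). The acid phosphatase gene Acp5 (9.11 against 118 CPM) and Spic, the gene of a red-pulp macrophage transcription factor (4.56 against 60.4), were lower as well. Cxcl9 stood at 217 against 600.0 CPM, Ccr2 at 134 against 96.2 and Ly6c2 at 407 against 240. The log2 ratio of Ccr2 (0.48) became −0.003 with a Leiden resolution of 0.5 and that of Ly6c2 (0.77) −0.16 without the response lists. Mrc1 (620 against 138.5 CPM) had a log2 ratio of 2.16, and −0.14 with a fixed minimum of 1000 UMIs. Neutrophil markers had a median log2 ratio of 4.47 (4.08 to 4.73), but −0.07 with that minimum.

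In cDC2-like cells alternative activation, chemokine, matrix and hypoxia genes were higher in the Treg-depleted than in the control tumor, and MHC class II genes were lower. Type I interferon response genes were lower, and the interferon gamma and lysosome lists lay inside the random range. The T helper 2 chemokine gene Ccl17 showed a large difference. The class, cluster 11 in both tumors, held 133 Treg-depleted cells with a median of 7471 UMIs and 265 control cells with a median of 7513 UMIs, and the median log2 ratio over 6298 genes was −0.16. The other dendritic cell classes had under 50 cells in the Treg-depleted tumor and were not compared.

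Alternative activation had a median log2 ratio of 2.30 (1.65 to 2.39), with 11 of 15 members at least 2-fold higher and none 2-fold lower, between 1.67 and 2.66 over the alternatives. Chemokines (0.93, 0.68 to 1.21, and 3.23 with the ambient profile subtracted), matrix remodelling (0.85, 0.72 to 1.25) and hypoxia and glycolysis (0.66, 0.54 to 0.80) also lay above every random list, and oxidative stress genes (0.50) at percentile 99.9. MHC class II (−0.63, percentile 0.12), the type I interferon response (−0.48, 0.45), cell cycle genes (−0.98, 0.72) and the cDC2 markers themselves (−0.95, 0.03) were lower. The remaining medians, oxidative phosphorylation (0.18, 96.2), lysosome (0.15, 95.1), inflammatory cytokines (0.11, 94.5), interferon gamma response (0.08, 95.02), unfolded protein response (0.07, 87.1), MHC class I (−0.10, 41.6), ribosomal proteins (−0.11, 12.3), heat shock (−0.28, 11.8) and co-signalling ligands (−0.39, 6.37), lay inside the random range.

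Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), 1 of the markers of the class, was counted at 10030.0 CPM (9846 to 10230.0) in Treg-depleted and 281 CPM (260 to 304) in control tumor cDC2-like cells. Ccl24 stood at 1660.0 CPM (1584 to 1739) against 22.4 (16.7 to 29.5) and Arg1 at 598 CPM (553 to 646) against 23.3 (17.5 to 30.5). Outside the lineage of the Treg-depleted tumor, Ccl24 and Arg1 stood at 228 and 118 CPM in cDC1-like, 355 and 255 CPM in neutrophil-like and 1243 and 798 CPM in the 16 CCR7 DC-like cells, so Arg1 in cDC2-like cells was not above every such class. Slc7a2 had 120 against 0 UMIs, at least 84.6-fold higher, and Retnla 134 against 1, a log2 ratio of 8.15 (5.64 to 13.46) that became 4.37 and 4.71 with the 2 ambient subtractions. Ambient RNA of the Treg-depleted tumor held Retnla at 1203 CPM and its cDC2-like cells 125 CPM. The costimulatory receptor gene Tnfrsf9 (134 against 9.68 CPM), the lipase gene Lpl (275 against 33.4), the fatty acid receptor gene Cd36 (192 against 22.4), Hmox1 (537 against 74.3) and Mmp12 (384 against 40.5) were higher. The cytokine gene Il1b (969 against 5559 CPM), the NK-type receptor gene Klrd1 (93.9 against 524), the peptide-loading modulator gene H2-Oa (37.2 against 162) and the surface receptor gene Cd7 (35.4 against 280) were lower. Mrc1 stood at 81.9 against 31.2 CPM, Ly6c2 at 443 against 293 and Ccr2 at 68.8 against 129. For Cxcl9 (411 against 376.5 CPM) and C1qa (103 against 96.3) the interval of the ratio held 1. Apoe (20.5 against 231 CPM) was read as background, since cDC1-like cells of the control tumor held 219 CPM, and its log2 ratio of −3.50 became 1.54 with ambient RNA subtracted.

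**Figure D3:**
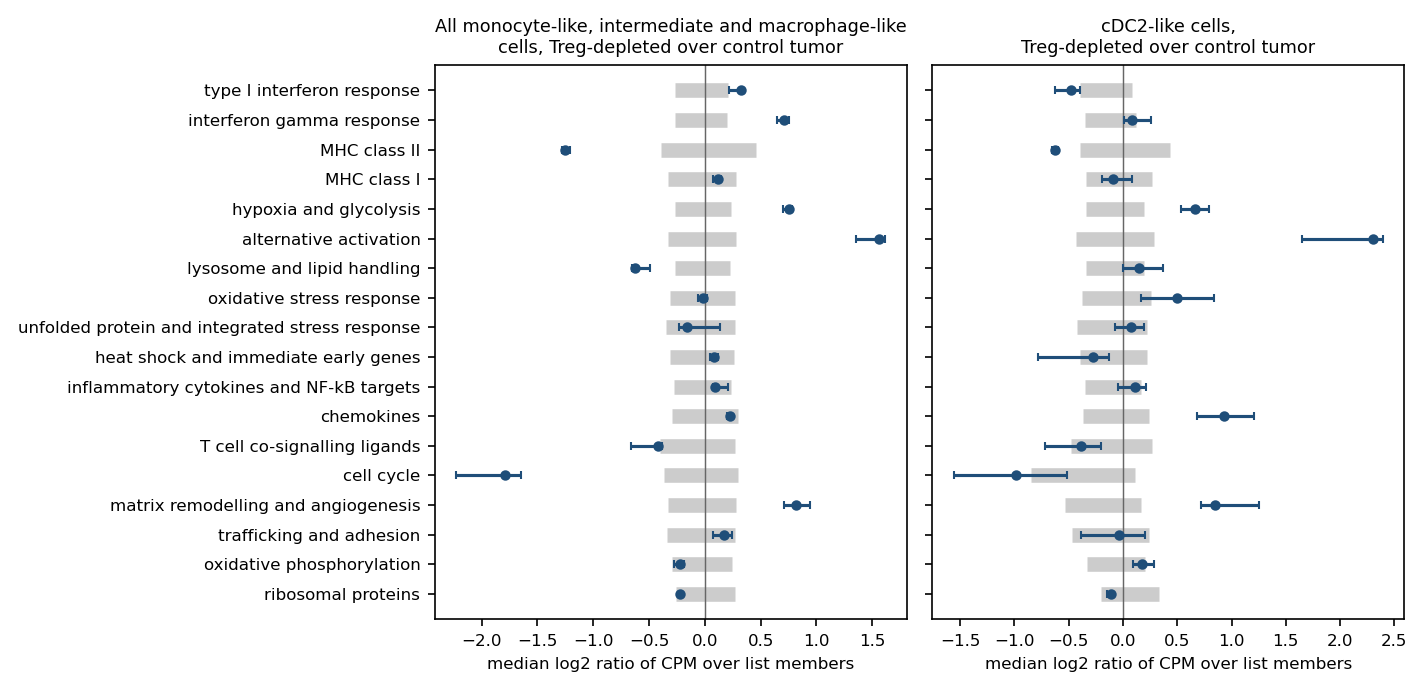
Median log2 ratio of CPM over the members of each gene list, Treg-depleted over control tumor, in the whole monocyte-to-macrophage lineage (left) and in cDC2-like cells (right); dots give list medians with 95% counting intervals and grey bars the central 95% of 10000 expression-matched random lists. Alternative activation stood highest in both (1.56 and 2.30), and MHC class II (−1.26 and −0.63) and cell cycle genes (−1.79 and −0.98) lay below 0 in both.

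Within each tumor, macrophage-like cells had higher chemokine and alternative activation genes than monocyte-like cells, and lower interferon and inflammatory genes. Cell cycle genes were higher in macrophage-like cells of both tumors, though only 7 members could be measured in the Treg-depleted tumor. MHC class II genes lay above every random list in the control tumor and inside the random range in the Treg-depleted tumor. Genes of the monocyte and macrophage markers define the classes and are left out. All-gene medians were 0.27 over 10109 genes in the control and 0.32 over 6578 genes in the Treg-depleted tumor.

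In the control tumor cell cycle genes had a median log2 ratio of 3.34 (2.92 to 3.67), with 22 of 24 members at least 2-fold higher, between 2.64 and 4.18 over the alternatives. Chemokines (1.56, 1.48 to 1.63), MHC class II (1.56, 1.54 to 1.58), alternative activation (1.53, 1.26 to 1.88), hypoxia and glycolysis (0.89) and lysosome and lipid handling genes (0.86) lay above every random list. Over the alternatives chemokines ran from 0.66 to 1.73, MHC class II from 0.79 to 1.74 and alternative activation from 0.86 to 2.14. The type I interferon (−0.57) and interferon gamma (−0.66) lists lay below every random list, and inflammatory cytokines (−0.80) lay at percentile 0.01. Dendritic markers were higher at the macrophage-like end as well: CCR7 DC markers had 3.16 (2.66 to 3.76), with 12 of 12 at least 2-fold higher, cDC1 markers 2.51 and cDC2 markers 1.48. With a split at a z difference of 1 the CCR7 DC markers had 0.38 and the cDC2 markers −0.54. The monocyte chemokine gene Ccl8 stood at 1443 CPM in macrophage-like and 20.8 CPM in monocyte-like cells, the platelet factor gene Pf4 at 882 against 19.8, Arg1 at 235 against 6.30, H2-Ab1 at 9076 against 3104 and Cxcl9 at 600.0 against 406. Lower were Cxcl10 (299 against 2436 CPM), the glutathione reductase gene Gsr (33.9 against 619) and the neutrophil antigen gene Cd177 (1.995 against 120).

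In the Treg-depleted tumor alternative activation had 2.34 (1.68 to 2.41), with 13 of 17 members at least 2-fold higher, but 0.24 with a fixed minimum of 1000 UMIs. The interferon lists were far lower at the macrophage-like end, −1.52 (−1.74 to −1.43) for type I, where 29 of 34 members were at least 2-fold lower, and −1.68 (−1.78 to −1.50) for interferon gamma. Their ranges over the alternatives were −1.84 to −1.25 and −2.003 to −1.48. The monocyte-like class of this tumor was cluster 9, with interferon-inducible genes among its leading genes. The lower values therefore cannot be credited to the macrophage-like end alone. Chemokines had 1.05 (percentile 99.99), cell cycle genes 2.32 (98.8), heat shock genes 0.74 (99.9) and MHC class II 0.70 (94.4). With the fixed minimum chemokines had 0.27 and cell cycle genes 0.80, and MHC class II ran from 0.35 to 1.69 over the alternatives. Ccl17 stood at 1822 against 21.99 CPM, Retnla at 2360.0 against 36.8, Ccl8 at 3927 against 151.5 and Arg1 at 3889 against 763, where the log2 ratio of 2.35 became −0.03 with a fixed minimum of 1000 UMIs. The interferon-inducible DNA sensor gene Ifi205 (192 against 1749 CPM) and the serpin gene Serpina3g (78.1 against 754) were lower. Dendritic markers were higher in this class as well. The cDC2 markers, which include Ccl17, had 2.94 (2.49 to 3.36), with 6 of 8 at least 2-fold higher, between 1.39 and 3.74 over the alternatives. Markers of migrating dendritic cells had a list median of 5.68 (4.98 to 6.06) and the chemokine receptor gene Ccr7 at 339 against 6.21 CPM, but the list median became −1.28 with that minimum.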

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

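The tests on Apoe and on Arg1, Retnla and Ccl24 were chosen only after those results had been seen, and the tests on the inflammatory genes before. Macrophage-like and monocyte-like cells differed in opposite directions in the 2 tumors for 4 lists, taken as those whose counting intervals lay on opposite sides of 0, as median log2 ratios of macrophage-like over monocyte-like cells. MHC class I had 0.13 in the control and −0.56 in the Treg-depleted tumor, the oxidative stress response 0.25 and −0.58, ribosomal proteins 0.15 and −0.22, and neutrophil markers −4.12 and 0.79. No list lay outside the random range in both tumors: ribosomal proteins lay inside it in both, MHC class I and the oxidative stress response in the control tumor and neutrophil markers in the Treg-depleted tumor. The differences between the tumors were not tested, since each tumor had 1 library. Neutrophil markers were furthest apart, and in the Treg-depleted tumor they had −1.16 when the response lists were left out of the clustering.

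Apoe stood far lower across the lineage of the Treg-depleted tumor. The log2 ratio was −4.92 after the ambient profile was subtracted at the share seen in cells outside the lineage, against −4.87 without. That share was at most 4.57% in the control and 7.55% in the Treg-depleted tumor, estimated from genes that include Apoe. A share this small could not have removed the difference. The values argue against ambient RNA as the whole cause only if the share in lineage cells was as small. The line between classes was argued against as well: the highest Apoe level of a lineage cluster of the Treg-depleted tumor was 0.344 of the lowest of the control tumor (803 and 2334 CPM). Treg depletion, the FoxP3 DTR genotype and differences between animals or libraries that have nothing to do with Treg cells remain open and untested. Lower lipid carrier expression with Treg depletion is therefore only a hypothesis that a replicated design could test.

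Arg1, Retnla and Ccl24 stood higher in the Treg-depleted tumor. With the ambient profile subtracted in the same way their median log2 ratio was 4.16. This argues against ambient RNA as the whole cause under the same limit, with Ccl24 among the genes that gave the share. Ambient RNA did carry Arg1 (3177 CPM) and Ccl24 (4875 CPM) there, against 162 and 66.1 CPM in the control tumor. A different mixture of the classes was argued against by the lowest log2 ratio of the 3 genes within any of them, 3.90, and another mixture of the control tumor's clusters by the level over the lineage of the Treg-depleted tumor, at least 2.90 times that of the highest control cluster (Arg1; 8.24 for Retnla and 50.6 for Ccl24). In the clusters 1, 0 and 9, found in both tumors, Arg1 was 354, 6412 and 763 CPM in the Treg-depleted and 361, 1692 and 196 CPM in the control tumor, Retnla 1557, 176 and 36.8 against 58.3, 0 and 1.38 CPM, and Ccl24 was higher in each, so Treg depletion, genotype, library and cell states present in only 1 tumor remain open and untested.

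Inflammatory and chemokine genes stood higher in tumor than in blood monocyte-like cells. For Cxcl2, a few cells carrying all of the signal was argued against. A Cxcl2 UMI was seen in 57.1% of thinned control tumor monocyte-like cells, above the background share in plasmacytoid DC-like cells given earlier. Only this abundant gene was tested, so scarcer members of the lists could still rest on few cells. Digestion of the tissue cannot be told apart from the tumor itself, because only the tumors were digested: heat shock and immediate early genes had a median log2 ratio of 0.74 (0.53 to 1.05) in cDC2-like cells of the control tumor over those of blood, and the inflammatory list was higher there too (3.10, 2.93 to 3.52). The tissue itself remains a biological explanation that was not tested.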

How the results depend on the processing

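No paired analysis was possible because each group has 1 library and no replicate numbers. The alternatives that moved the class boundary, left out blood cluster 5 or took the ambient share from cells outside the lineage were chosen only after the data had been seen. The 28 main results of the comparisons had 179 values under the alternatives: 91 lay within the counting interval of the reported value, 88 moved beyond it and 0 changed direction. A share has no sign that could change, and a comparison that lost its class gave no value. The last count therefore bears only on ratios that had values. Where a value below moved or changed direction, the cause was not tested. Changes of direction are all listed for values of at least 2-fold, and in part for smaller ones at the end. Ratios are log2 and shares percent, and macrophage-like shares of the lineage are given as control and then Treg-depleted tumor.

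With a fixed minimum of 1000 UMIs those shares were 24.3 and 2.79. Medians were 6.52 for chemokines in tumor over blood monocyte-like cells, 1.12 for the interferon gamma response in Treg-depleted over control tumor monocyte-like cells, and for alternative activation 0.97 in macrophage-like and 2.66 in cDC2-like cells between tumors and 0.24 in macrophage-like over monocyte-like cells of the Treg-depleted tumor. Direction changed between the tumors in macrophage-like cells for matrix remodelling (−0.11), neutrophil markers (−0.074), Cd74 (0.38), H2-Aa (0.21), H2-Ab1 (0.50), H2-DMb1 (0.48), Mmp13 (−0.56) and Mrc1 (−0.14), and within the Treg-depleted tumor for CCR7 DC markers (−1.28) and Arg1 (−0.032). Shares were 64.7 monocyte-like, 14.5 nonclassical and 2.91 neutrophil-like in blood, 19.8 monocyte-like, 46.4 intermediate, 21.2 macrophage-like and 5.97 cDC2-like in the control tumor, and 73.5 intermediate, 2.44 macrophage-like and 5.87 neutrophil-like in the Treg-depleted tumor.

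Without doublet removal the macrophage-like shares were 32.2 and 0.98 and chemokines in tumor over blood 6.66. Blood held 65.3 monocyte-like and 12.9 nonclassical, the control tumor 41.6 intermediate and 27.9 macrophage-like, and the Treg-depleted tumor 77.5 intermediate, 0.87 macrophage-like, 1.87 cDC1-like and 3.92 neutrophil-like. With at most 5% mitochondrial UMIs they were 38.2 and 1.78, with chemokines at 6.56. Blood then held 64.2 monocyte-like, 16.5 nonclassical, 7.47 cDC2-like, 0.0 plasmacytoid DC-like and 1.38 B cell-like, the control tumor 35.5 intermediate and 33.1 macrophage-like, and the Treg-depleted tumor 13.02 monocyte-like, 47.3 intermediate, 1.09 macrophage-like, 1.38 cDC2-like and 1.99 cDC1-like. In both settings the macrophage-like class of the Treg-depleted tumor had under 50 cells (34 and 38), so its comparisons gave no value.

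With a Leiden resolution of 0.5 the macrophage-like shares were 78.5 and 5.15. Chemokines in tumor over blood had 6.24, alternative activation in macrophage-like cells between tumors 0.46, cell cycle genes −0.67 over the lineage between tumors and 2.79 in macrophage-like over monocyte-like cells of the control tumor. Direction changed between tumors for C1qa in intermediate cells (0.22), cell cycle (2.26) and matrix remodelling (−0.11) in macrophage-like cells, and Ptgs2 (−0.37) and Rsad2 (−0.25) over the lineage. Blood held 51.8 monocyte-like and 27.3 nonclassical, the control tumor 1.99 intermediate and 68.3 macrophage-like, and the Treg-depleted tumor 0.0 monocyte-like, 41.8 intermediate, 2.27 macrophage-like and 1.24 cDC2-like. There 1898 of 3785 cells were unnamed, against 66 in the reported values, and 1021 of 3471 with at most 5% mitochondrial UMIs. With no monocyte-like class, comparisons that need it gave no value.

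Clustering without the response lists gave a macrophage-like share of 70.5 in the control tumor, 0.86 for the interferon gamma response in monocyte-like cells between tumors, 2.64 for cell cycle and 1.57 for alternative activation in macrophage-like over monocyte-like cells of the control and the Treg-depleted tumor, and a changed direction for Cxcl9 in intermediate cells (0.65). Blood held 49.2 monocyte-like and 29.2 nonclassical, the control tumor 23.1 monocyte-like, 1.83 intermediate and 59.7 macrophage-like, and the Treg-depleted tumor 14.6 monocyte-like, 66.7 intermediate and 3.73 neutrophil-like.

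Intermediate cells counted as macrophage-like gave shares of 80.4 and 87.0, alternative activation at 1.63 between tumors and 1.52 within the Treg-depleted tumor, and cell cycle at 2.81 within the control tumor. A split at a z difference of 1 gave 18.3 and 0.0, so no macrophage-like comparison of the Treg-depleted tumor, cell cycle at 3.80 within the control tumor, and a changed direction there for cDC2 markers (−0.54). With the control tumor cells of cluster 9 counted as monocyte-like, the interferon gamma response had 0.96 in monocyte-like cells between tumors, type I interferon genes 0.39, and Ifit1 changed direction (−0.009, from 2.53). Blood monocyte-like cells without cluster 5 kept chemokines in tumor over blood at 5.88, while MHC class II had 2.12 (from −0.02).

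Scaling by the median of gene ratios gave 6.56 for chemokines in tumor over blood and 2.46 for alternative activation in cDC2-like cells. Subtracting the ambient profile gave 5.35 for chemokines, −2.61 for cell cycle over the lineage and 4.18 within the control tumor, and changed the direction of Mmp12 (−0.46) and Mrc1 (−2.68) in monocyte-like cells between tumors. Its share rested on only 20 and 10 ambient UMIs of melanoma genes in the control and Treg-depleted tumor, and ran from 2.22% to the ceiling of 50%. At the share seen in cells outside the lineage, chemokines had 7.48 and alternative activation within the Treg-depleted tumor 2.43, and the direction changed for Mrc1 in monocyte-like cells (−3.94) and Apoe in cDC2-like cells (1.54) between tumors. The mean over cells of CPM gave alternative activation at 2.03 in macrophage-like and 2.57 in cDC2-like cells and cell cycle at −1.26 over the lineage. Every detected list member moved none of the main results.

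Named genes kept their sign in 446 of 456 values with the fixed minimum, 384 of 387 without doublet removal, 299 of 302 at 5% mitochondrial UMIs, 246 of 254 at resolution 0.5, 451 of 457 without the response lists, 455 of 457 with median scaling, 454 of 457 as means over cells, 451 and 450 of 456 with the 2 ambient subtractions, 187 of 187 with intermediate cells as macrophage-like, 117 of 117 at a z difference of 1, 85 of 87 with cluster 9 counted as monocyte-like and 87 of 89 without blood cluster 5. Lists, many with medians near 0, kept theirs in 130 of 149, 108 of 114, 82 of 92, 70 of 84, 132 of 149, 124 of 149, 140 of 149, 144 and 141 of 149, 74 of 78, 42 of 43, 18 of 21 and 19 of 23, and in 144 of 149 with every detected member.

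Among smaller values, direction changed with the fixed minimum within the Treg-depleted tumor for Apoe (−0.97 to 2.08), matrix remodelling (0.87 to −0.86), hypoxia (0.61 to −0.25) and Ccr2 (−0.31 to 0.28), and in macrophage-like cells between tumors for MHC class II (0.29) and CCR7 DC markers (0.48 to −2.31). Over the lineage, resolution 0.5 gave −1.44 for Ifit1 (from 0.66), −0.63 for Ifi205 (from 0.72) and 0.16 for Ccr2, and at most 5% mitochondrial UMIs −0.55 for Ifit1 and 0.11 for Ccr2. Without the response lists, neutrophil markers in monocyte-like cells between tumors went from −0.86 to 1.35 and Ccr2 in intermediate cells from −0.33 to 1.46, and in macrophage-like cells Ly6c2 went from 0.77 to −0.16. Ccr2 in macrophage-like cells between tumors went from 0.48 to −0.003 at resolution 0.5, and classical monocyte markers from 0.88 to −0.11. C1qa in monocyte-like cells between tumors went from −0.41 to 4.90 at the ambient share from cells outside the lineage.

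Depth limits the scarce genes: Inhba had 0 UMIs in blood monocyte-like cells and Slc7a2 in control tumor cDC2-like cells, so only bounds can be given there, and the Treg-depleted macrophage-like class, with 1536563 UMIs against 14534049, sets the width of its intervals.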

Other observations

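The cDC2-like cells of the control tumor differed from those of control blood in much the same lists as monocyte-like cells. Chemokines had a median log2 ratio of 4.32 (3.80 to 4.52), with 17 of 19 members at least 2-fold higher, the interferon gamma response 3.99 (3.20 to 4.12), and matrix remodelling 3.09 (2.77 to 3.54). Hypoxia and glycolysis genes stood higher in the tumor (1.31, 1.22 to 1.42), with 16 of 24 members at least 2-fold higher and none 2-fold lower. The type I interferon response, at −0.30 in monocyte-like cells, was 0.59 in cDC2-like cells, with 14 of 34 members at least 2-fold higher. Lower in the tumor was the trafficking and adhesion list (−0.66, percentile 1.34).

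Blood monocyte-like cells of the tumor-bearing mice were not uniform. Besides the main cluster of 1435 cells there was 1 of 799 cells that scored higher on macrophage (1.39) than on classical monocyte markers (0.30), with C1qb, Ms4a7 and H2-Ab1 among its leading genes, and 1 of 201 cells led by interferon-inducible genes. A C1qb UMI was counted in 3.37% of all blood monocyte-like cells, which at this depth does not limit how many carried the transcript. Without the 799 cells the MHC class II median of tumor over blood monocyte-like cells was 2.12 in place of −0.02. An interferon-led group of 96 cells also existed among the intermediate cells of the control tumor.

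Erdr1, a gene of the region shared by the X and Y chromosomes, stood between 34.0 and 186 CPM in the lineage clusters of the Treg-depleted tumor and between 0 and 1.82 CPM in those of the control tumor. The gap was not confined to the lineage: Erdr1 stood at 44.7 against 0.44 CPM in cDC2-like and 48.0 against 0 CPM in cDC1-like cells. Ambient RNA of the Treg-depleted tumor held it at 276 CPM against 2.1 CPM, and the haemoglobin transcript Hbb-bs at 2564 against 4.3 CPM. No explanation for it was tested.

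Cells rich in melanoma transcripts were nearly absent. Cells with at least 10 UMIs of melanoma genes numbered 0 in blood, 4 in the control tumor (0.108%, median 22411.5 UMIs) and 1 in the Treg-depleted tumor (0.026%). All 4 control tumor cells also had UMIs of the leukocyte gene Ptprc and the myeloid gene Lyz2. The 1 Treg-depleted cell had a Lyz2 UMI and no Ptprc UMI. An unnamed cluster part of 49 Treg-depleted tumor cells was nevertheless led by Dct, Mlana, Pmel and Tyrp1, pigment genes of melanoma cells. Its levels were summed over cells, so few cells can set the leading genes. How many of the 49 carried them was not counted.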
